A study of Homo sapiens with 9 samples.

How the data were processed

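The 9 libraries come from A375 melanoma cells given 0, 20 or 40 mM metformin, with 3 libraries per dose. Per the labels' protocols, total RNA was taken with TRIzol, polyadenylated RNA was captured with oligo(dT), and strand-specific libraries made with dUTP and UDG were sequenced paired-end on an Illumina NovaSeq. Read counts per gene and library are given in the deposited table, per the file headers. FPKM per gene and library are given in the same deposited table, per the file headers. StringTie 2.1.6 is named per the submitters' processing notes, which do not say which values it made. The aligner, the annotation, the genome build, the strand used in counting and any filtering are not given in the sources used here. Of the 37118 gene IDs, 35955 occur in GENCODE release 29 and 22406 (60.4%) have the same start and end there.

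The test foreseen before the data were examined was limma on log2(FPKM + 1), unless the file held counts. It held counts, so the main test was edgeR's quasi-likelihood test on the counts, and the limma test was kept as an alternative. Genes with a mean FPKM of at least 1 over the 9 libraries were tested, 12394 in all, holding 98.74% of the counts. Libraries were scaled by TMM and all 9 entered 1 fit, from which the 3 comparisons between doses were drawn. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05, and the words rose and fell refer to calls. The SE of a log2 fold change is its size over the square root of its F. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Library totals ran from 65738242 to 75629413 counts, a depth at which the spread between libraries and not counting error sets the precision of well-expressed genes; the SE printed beside each change gives it.

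The 28 gene lists were written before the data were examined. They cover ferroptosis and iron, stress responses, lipid synthesis, energy metabolism and the respiratory chain, the cell cycle and cell death, melanoma cell state, signalling and inflammation, lysosomes, ribosomes, and markers of other cell types. Some lists share members, so they are not independent. FTH1 and FTL stand in ferroptosis defence, iron handling and NRF2 targets, and SLC7A11 in ferroptosis defence, NRF2 targets and ATF4 targets. Lists were tested with limma's camera on log2 CPM (prior count 1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the 28 lists of a comparison. The count of members called was taken over all tested genes and, separately, adjusted over the list alone. Over all tested genes, 31.6% were called at 20 against 0 mM, 56.2% at 40 against 0 mM and 29.3% at 40 against 20 mM. A count near these shares does not set a list apart.

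The rule for naming genes was also fixed before the data were examined. It names the 6 largest rises and falls of each dose against 0 mM and the 4 largest between the doses, among called genes with a mean FPKM of at least 5 in the higher group and no overlap between the libraries of the groups. From each list it takes up to 3 called members, 4 in the ferroptosis lists, or the 2 with the smallest p where none was called. It adds 14 genes chosen in advance. Some genes named by this rule, and 1 list, are not reported here. NUPR1 and ADM2 are named as members of the ATF4 list.

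The alternatives planned before the data were examined were no filter, a filter at 5 FPKM, scaling by median of ratios or to TPM, DESeq2, limma on log2 FPKM with 3 pseudocounts, quantile normalization, library weights, other priors, only the 6 libraries compared, a replicate block, other thresholds, and leaving out each library in turn. Chosen after seeing the data were the member counts without replicate 3 of 40 mM and pathways of the deposited annotation. Shared controls were examined with 20 simulations of unchanged groups, and the 10 splits of the 6 libraries of each comparison were run. A left-out library leaves 2 in its group.

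The tests were tested on simulated data with the depth and spread of the 9 libraries, with 50 genes changed at each fold among 12394. For 20 against 0 mM edgeR recovered 82% of 2-fold changes, for 40 against 0 mM 90%, and for 40 against 20 mM 98%; at 4-fold it was 100%, 100% and 98%. False calls made up 5.49%, 3.37% and 4.37% of its calls, against 17.3%, 15.2% and 13.4% for DESeq2 and 6.45%, 4.29% and 5.23% for limma. The simulated spread was edgeR's own estimate, and most simulated genes were unchanged, while 31.6%, 56.2% and 29.3% were called in the real data. These values therefore do not rank the tools on the real data. The camera test found a list of 25 genes shifted by 0.5 in each comparison and called 0 of 27 unchanged lists. Simulated genes were drawn independently, so this does not test lists whose genes vary together. Estimated correlations of the real lists reached 0.849, and splits of the libraries other than the real ones called up to 12 lists. No library was a copy of another, and every column was matched to a sample.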

Results

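Transcript levels were measured by RNA sequencing in A375, an established human melanoma cell line that carries an activating BRAF mutation. Cells received metformin at 0, 20 or 40 mM, with 3 libraries per group and 9 in all. Metformin is a biguanide used against type 2 diabetes whose known targets include complex I of the mitochondrial respiratory chain. The study's stated subject is ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. Total counts per library were 75400950, 74816762 and 75043512 at 0 mM. They were 74274409, 71989352 and 73899397 at 20 mM, and 75518957, 75629413 and 65738242 at 40 mM. Of 37118 genes listed, 12394 had a mean FPKM of at least 1 and were tested. Nothing in the labels says that the replicates came from separate cultures, so each p-value measures only the spread between these libraries, which may be technical. Levels are given as mean FPKM ± SD and changes as log2 fold change ± SE, each with n = 3 per group. Positions are those of the deposited table, whose genome build is not given in the sources used here.

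The first principal component held 45.1% of the variance and ordered the libraries by dose. Replicate 3 of 40 mM stood apart from the other 40 mM libraries on the second component, at -22.6 against 17.7 and 15.2. Mitochondrially encoded genes took 4.36% of its counts, against 3.01% and 3.27% in replicates 1 and 2, and cytosolic ribosomal protein genes 3.54%, against 3.87% and 4.05%.

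At 20 mM against 0 mM, which asks what the lower dose changed, all 35 measured ATF4 targets rose, with a median log2 fold change of 1.19. ATF4 is the transcription factor of the amino acid and integrated stress response. CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956512), went from 4.70 ± 0.331 to 25.9 ± 2.39 FPKM, a change of 2.46 ± 0.08 (adjusted p = 3.3e-08). DDIT3, the stress transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose from 8.73 ± 0.661 to 44.5 ± 6.48 FPKM (2.34 ± 0.12, adjusted p = 3.7e-07). Rises of similar size were seen for the stress cytokine GDF15 (2.46 ± 0.19), asparagine synthetase ASNS (from 15.5 ± 0.764 to 62.1 ± 7.04 FPKM) and the pseudokinase TRIB3 (1.90 ± 0.07). NUPR1, a small stress-response protein (ENSG00000176046, chromosome 16, 28532708 to 28538974), rose by 3.73 ± 0.14 and the peptide hormone gene ADM2 by 2.99 ± 0.10, both from under 1 FPKM. ATF4 itself rose by 0.59 ± 0.04. The ATF4 list passed the camera test (adjusted p = 1.7e-38, and adjusted p = 0.018 with an estimated correlation).

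Among genes of ferroptosis, SLC7A11, the cystine importer of system xc- (ENSG00000151012, chromosome 4, 138164097 to 138242349), rose from 12.6 ± 0.395 to 28.6 ± 1.39 FPKM at 20 mM (1.18 ± 0.05, adjusted p = 1.2e-07). GPX4, the peroxidase that reduces lipid hydroperoxides (ENSG00000167468, chromosome 19, 1103926 to 1106788), was at 29.04 ± 1.08 and 29.9 ± 1.02 FPKM (0.04 ± 0.05, adjusted p = 0.58). ACSL4, which loads polyunsaturated fatty acids into lipids (ENSG00000068366, chromosome X, 109624244 to 109733392), fell by 0.29 ± 0.07 (adjusted p = 0.0084). In the ferroptosis defence list 9 of 23 measured members rose and 2 fell, the same counts as adjusted over the list alone. Its risers included the glutathione transferase MGST1 (0.58 ± 0.05), GCH1, the first enzyme of tetrahydrobiopterin synthesis (0.57 ± 0.13), and thioredoxin reductase TXNRD1 (0.53 ± 0.13). The list did not pass the camera test (adjusted p = 0.094). With fry, which called most lists at 20 mM, the defence list was called as rising (adjusted p = 0.0013). The ferroptosis promotion list was not called with fry (adjusted p = 0.072). In the ferroptosis promotion list 3 of 21 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.91), and 3 fell without replicate 2 of 0 mM or without replicate 1 or 3 of 20 mM. The glutamine carriers SLC38A1 (0.85 ± 0.04) and SLC1A5 (0.82 ± 0.04) and the NRF2 repressor BACH1 (0.40 ± 0.08) rose, and the polyamine acetyltransferase SAT1 fell by 0.75 ± 0.08.

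Other genes chosen in advance moved as follows at 20 mM. Ferritin heavy chain FTH1 rose by 0.38 ± 0.07, and the antioxidant regulator NFE2L2 by 0.29 ± 0.06. Transferrin receptor TFRC (-0.03 ± 0.07, adjusted p = 0.74), heme oxygenase HMOX1 (0.51 ± 0.32, adjusted p = 0.26, and 0.28 without replicate 1 of 20 mM) and the thioredoxin inhibitor TXNIP (-0.16 ± 0.15, adjusted p = 0.45) did not pass the test. TXNIP was at -0.25 and -0.09 without replicates 1 and 3 of 0 mM and at -0.07 and -0.28 without replicates 1 and 3 of 20 mM. With 1 library left out TFRC ran from -0.06 to 0.00 and GPX4 from 0.01 to 0.06. Mitochondrial superoxide dismutase SOD2 was called at 0.20 ± 0.05 (adjusted p = 0.02), and not without replicate 3 of 0 mM (0.17, adjusted p = 0.069) or replicate 2 of 20 mM (0.18, adjusted p = 0.075). PTGS2, the cyclooxygenase often read as a ferroptosis marker, had a mean FPKM of 0.372 and was not tested. Its counts were 74, 111 and 77 at 0 mM, 176, 166 and 107 at 20 mM, and 296, 288 and 164 at 40 mM.

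**Figure D1:**
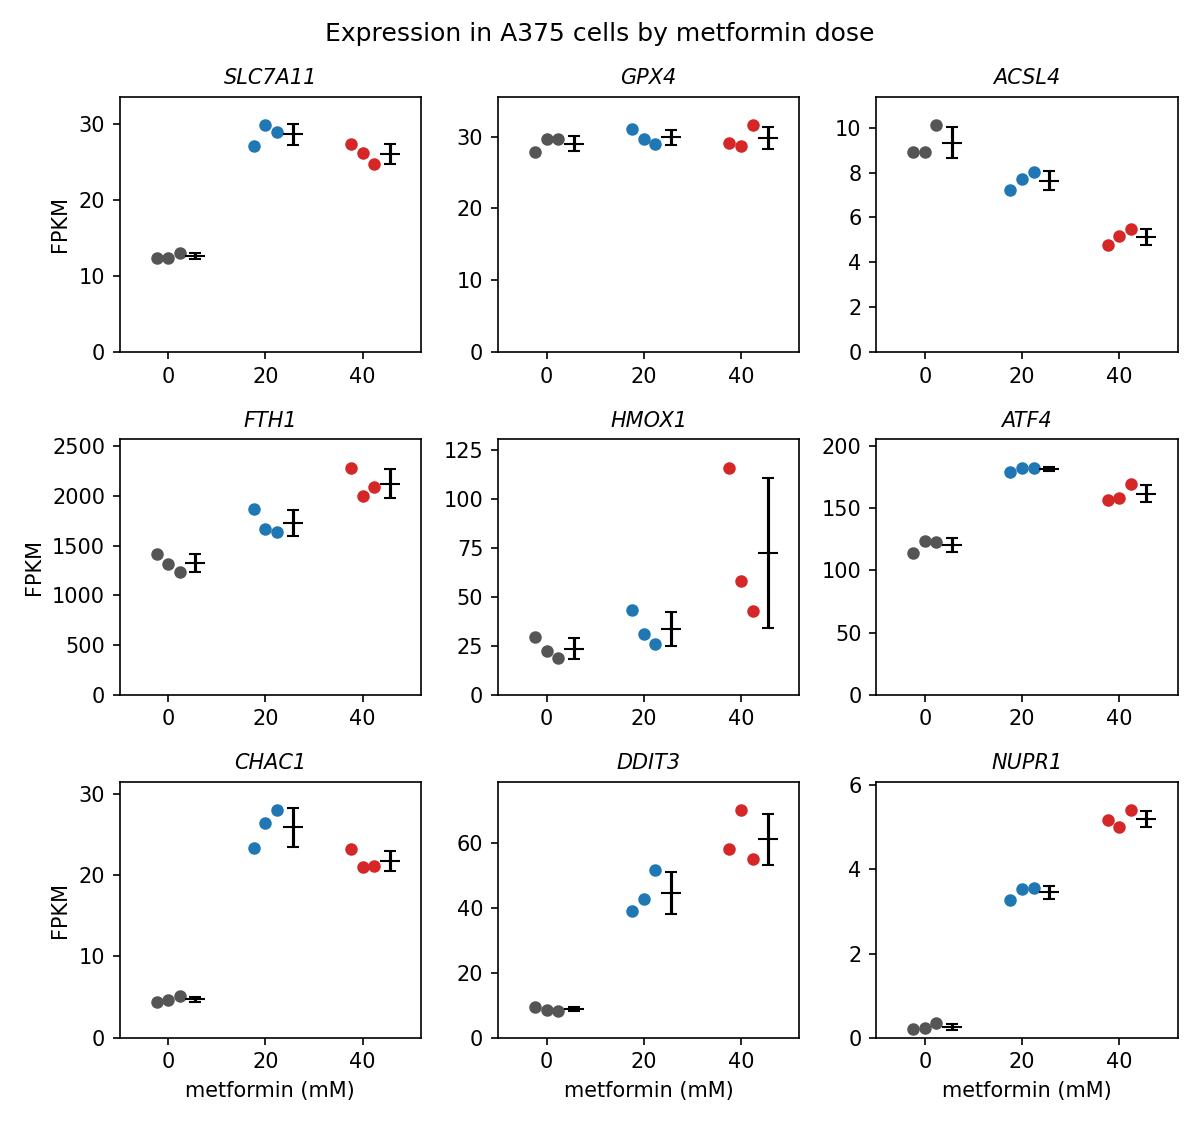
FPKM (vertical axes, each from 0) of 9 genes at 0, 20 and 40 mM metformin; each point is 1 library and the bars give the mean ± SD of 3. SLC7A11 lies near 12.6 at 0 mM and at 28.6 and 26.0 at the higher doses, GPX4 lies at 29.9 and 29.8 at those doses, and ACSL4 goes from 9.33 to 5.14.

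BEST1, an anion channel gene (ENSG00000167995, chromosome 11, 61950063 to 61964461), had the largest rise named at 20 mM, from 0.772 ± 0.633 to 13.5 ± 0.459 FPKM (4.11 ± 0.50, adjusted p = 0.00018). Without replicate 1 of 0 mM its log2 fold change was 5.03, within a range of 3.74 to 5.03 without single libraries. It overlaps FTH1 (ENSG00000167996, 61959718 to 61967634) on the opposite strand, and whether the counting used strand is not given in the sources used here, so its level is uncertain. Of the 6 largest falls named, 5 were mitochondrial tRNA genes, namely MT-TF (-2.59 ± 0.30), MT-TV (-2.44 ± 0.30), MT-TT (-1.54 ± 0.21), MT-TQ (-1.28 ± 0.15) and MT-TM (-1.25 ± 0.19). The other was TFAP2B, a transcription factor of neural crest cells, which fell by 1.76 ± 0.21. Mature tRNAs lack poly(A) tails and nuclear copies of mitochondrial DNA can share their reads, so these levels are uncertain too.

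Genes of DNA synthesis fell at 20 mM: 22 of 28 measured S phase genes fell and none rose, also adjusted over the list alone (camera adjusted p = 1.4e-10, and adjusted p = 0.21 with an estimated correlation). Thymidylate synthase TYMS fell by 0.67 ± 0.06, the helicase subunit MCM5 by 0.58 ± 0.04 and GINS2 by 0.52 ± 0.06. Of 26 lysosome and autophagy genes, 20 rose and none fell, 21 adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.066 with an estimated correlation), among them WIPI1 (0.66 ± 0.10), GPNMB (0.56 ± 0.05) and MAP1LC3B (0.53 ± 0.06). Ribosome biogenesis genes fell in 15 of 24 cases, 16 adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.21 with an estimated correlation), with the nucleolar proteins NOP56 (-0.52 ± 0.05) and NCL (-0.41 ± 0.04). Heat shock genes fell in 11 of 17 cases, 14 adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.21 with an estimated correlation). They included the constitutive chaperone HSPA8 (-0.70 ± 0.07) and the near-identical HSPA1A (-0.67 ± 0.14) and HSPA1B (-0.65 ± 0.14), whose reads may be split between them.

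Cholesterol synthesis genes fell in 14 of 24 cases and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00054, and adjusted p = 0.32 with an estimated correlation). Without replicate 2 of 20 mM 9 fell. HMGCS1 fell by 0.66 ± 0.14. In the TCA cycle list 9 of 23 fell, 11 adjusted over the list alone, led by OGDH (-0.47 ± 0.06) and SDHA (-0.25 ± 0.04) (camera adjusted p = 0.0055, and adjusted p = 0.21 with an estimated correlation). Without any 1 of the 6 libraries compared, 3 or 4 fell, and with TPM scaling 3. Hypoxia response genes rose in 9 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.0063, and adjusted p = 0.21 with an estimated correlation), including the angiogenic factor VEGFA (1.10 ± 0.04) and NDRG1 (0.55 ± 0.07). NRF2 targets rose in 10 of 24 cases and fell in 2, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.54 with an estimated correlation). SLC7A11 and TXNRD1, named above, were among them, with TRIM16L (0.52 ± 0.13). MAPK pathway output genes rose in 7 of 19 cases and 1 fell, 7 and 2 adjusted over the list alone, with DUSP5 at 0.80 ± 0.14 and FOSL1 at 0.42 ± 0.08 (camera adjusted p = 0.049, and adjusted p = 0.33 with an estimated correlation). That call was lost with TPM scaling (adjusted p = 0.051), with library weights (0.058), with smaller pseudocounts in limma (0.052 and 0.053), without replicate 1 (0.077) or 2 (0.053) of 0 mM and without replicate 1 (0.089) or 3 (0.06) of 20 mM, within a range of 0.0026 to 0.089 over its alternatives.

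Lists not called at 20 mM are given next. Unfolded protein response genes fell in 9 of 19 cases and rose in 4, also adjusted over the list alone (camera adjusted p = 0.071), with XBP1 (0.78 ± 0.05) and HERPUD1 (0.59 ± 0.06) among the risers. Camera adjusted p was 0.86 for iron handling, 0.91 for fatty acid synthesis, 0.14 for glycolysis, 0.39 for G2/M phase, 0.5 for the BCL2 family, where PMAIP1 rose by 0.99 ± 0.08, and 0.91 for the melanocyte lineage. It was 0.069 for dedifferentiated and invasive melanoma genes, 0.069 for NF-kB and inflammatory genes, 0.48 for the interferon response and 0.62 for markers of other cell types. For nuclear-encoded complex I it was 0.79, for complexes III to V 0.5, for mitochondrially encoded genes 0.22 and for cytosolic ribosomal proteins 0.094. Without single libraries 4 of these were called: dedifferentiated melanoma genes (0.02 without replicate 1 of 0 mM and 0.014 without replicate 3 of 20 mM, range 0.0084 to 0.19) and NF-kB genes (0.038 and 0.042 without the same libraries, range 0.0094 to 0.32). The others were mitochondrially encoded genes (0.048 without replicate 3 of 0 mM, range 0.048 to 0.97) and ribosomal proteins (0.02 without replicate 3 of 0 mM, 0.034 without replicate 3 of 20 mM and 0.04 without replicate 3 of 40 mM, range 0.012 to 0.35). With no filter, glycolysis (0.018) and unfolded protein response genes (0.027) were called. Dedifferentiated melanoma (0.0084), NF-kB (0.0094) and ribosomal protein genes (0.012) were called with no filter too. Signs also differed for iron handling (median -0.01, mean 0.03), for ferroptosis promotion (median 0.01, test down) and for the melanocyte lineage (median -0.10, mean -0.02, test up).

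By edgeR's quasi-likelihood test, 3911 of 12394 genes differed between 20 and 0 mM, 2025 higher and 1886 lower. A change of at least 2-fold was seen in 98 of the higher and 31 of the lower genes. Leaving out replicate 3 of 40 mM, which enters through the shared estimate of the spread, gave 4966 genes, among them all 3911.

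At 40 mM against 0 mM, which asks what the higher dose changed, all 28 measured S phase genes fell, with a median of -0.54, and all 35 ATF4 targets rose, with a median of 1.06. TYMS fell from 102 ± 2.24 to 49.4 ± 4.59 FPKM (-1.08 ± 0.06), the cell cycle transcription factor E2F2 by 1.16 ± 0.12 and cyclin CCNE2 by 0.95 ± 0.09. NUPR1 rose from 0.258 ± 0.069 to 5.20 ± 0.194 FPKM (4.29 ± 0.14, adjusted p = 1.9e-08), DDIT3 to 61.1 ± 7.91 FPKM (2.77 ± 0.12, adjusted p = 5.3e-08), GDF15 by 2.88 ± 0.20 and CHAC1 by 2.18 ± 0.08. ATF4 rose by 0.40 ± 0.04. The camera test called S phase (adjusted p = 2.6e-13, and adjusted p = 0.11 with an estimated correlation) and ATF4 targets (adjusted p = 1.1e-20, and adjusted p = 0.045 with an estimated correlation), and both counts were the same adjusted over the list alone.

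SLC7A11 was at 26.0 ± 1.29 FPKM at 40 mM (1.01 ± 0.05, adjusted p = 1.1e-07), and GPX4 at 29.8 ± 1.56 (0.01 ± 0.05, adjusted p = 0.93). ACSL4 fell to 5.14 ± 0.358 FPKM (-0.89 ± 0.07, adjusted p = 2e-06). The ferroptosis defence list had 10 risers and 6 fallers among 23, with 11 and 6 adjusted over the list alone (camera adjusted p = 0.18). Ferritin light chain FTL rose by 0.87 ± 0.06 and GCH1 by 0.76 ± 0.13, while DHODH, the pyrimidine synthesis enzyme of the inner mitochondrial membrane, fell by 0.80 ± 0.09. The ferroptosis promotion list had 6 risers and 4 fallers among 21, also adjusted over the list alone (camera adjusted p = 0.82). Its median was -0.04 and its mean 0.04 with the test pointing up, and the median became 0.04 with TPM scaling, which moved that of all genes to 0.08. SLC38A1 (0.97 ± 0.04), SLC1A5 (0.80 ± 0.04) and BACH1 (0.75 ± 0.08) rose. With fry, which called most lists at 40 mM, both ferroptosis lists were called as rising (adjusted p = 0.0011 for defence and 0.0085 for promotion).

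HMOX1 rose from 23.5 ± 5.38 to 72.5 ± 38.6 FPKM (1.59 ± 0.33, adjusted p = 0.0017), and by 1.07 to 1.85 without any 1 library. FTH1 rose by 0.65 ± 0.07, NFE2L2 by 0.36 ± 0.06 and SOD2 by 0.33 ± 0.05. TFRC (-0.04 ± 0.07, adjusted p = 0.59) and TXNIP (0.27 ± 0.15, adjusted p = 0.15, and 0.17 without replicate 2 of 40 mM) did not pass the test. With 1 library left out TFRC ran from -0.10 to 0.04 and GPX4 from -0.04 to 0.03. Iron handling had 9 risers and 5 fallers among 23, also adjusted over the list alone (camera adjusted p = 0.43). NRF2 targets rose in 13 of 24 cases and fell in 3, with 14 and 3 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation). FTL and FTH1 have many processed pseudogenes, which makes their levels less certain.

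Other large rises at 40 mM were BEST1 (4.03 ± 0.49, 4.95 without replicate 1 of 0 mM, with FPKM of 17.3, 15.3 and 6.53 in replicates 1 to 3), the microtubule protein MAP1B (2.37 ± 0.07) and the small nuclear RNA RN7SK (3.48 ± 0.43), which has many genomic copies and no poly(A) tail and is uncertain. Falls were led by TFAP2B (-2.68 ± 0.22), MT-TF (-2.49 ± 0.30), MT-TV (-2.18 ± 0.30), MT-TT (-1.86 ± 0.22) and the glutamate transporter SLC1A1 (-2.19 ± 0.07). The readthrough gene PTGES3L-AARSD1 was called at -2.34 ± 0.71 (adjusted p = 0.016), but overlaps both of its parent genes and was not called without replicate 2 of 40 mM (-2.03, adjusted p = 0.059) or replicate 3 of 0 mM (-2.09, adjusted p = 0.0503).

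Lysosome and autophagy genes rose in 24 of 26 cases at 40 mM, 25 adjusted over the list alone (camera adjusted p = 2.7e-10, and adjusted p = 0.045 with an estimated correlation), with GPNMB at 1.16 ± 0.05, GABARAPL1 at 0.98 ± 0.06 and FNIP1 at 0.89 ± 0.06. NF-kB and inflammatory genes rose in 8 of 10 cases, also adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.11 with an estimated correlation), among them IL1A (1.69 ± 0.20), ICAM1 (1.05 ± 0.06) and IRF1 (0.99 ± 0.08). Hypoxia genes rose in 10 of 17 cases and fell in 2, 11 and 3 adjusted over the list alone, with NDRG1 (1.28 ± 0.07), BHLHE40 (1.14 ± 0.09) and VEGFA (1.12 ± 0.04) (camera adjusted p = 0.0067, and adjusted p = 0.2 with an estimated correlation). Of 18 dedifferentiated and invasive melanoma genes, 10 rose and 3 fell, also adjusted over the list alone, with the matricellular CCN1 at 1.74 ± 0.07, JUN at 1.60 ± 0.17 and TGFBI at 0.98 ± 0.04 (camera adjusted p = 0.014, and adjusted p = 0.45 with an estimated correlation). Interferon response genes rose in 5 of 13 cases, also adjusted over the list alone, with IFIT2 at 1.75 ± 0.14 and IFIT3 at 0.84 ± 0.08 (camera adjusted p = 0.041, and adjusted p = 0.2 with an estimated correlation). The interferon call was lost without replicate 2 of 40 mM (adjusted p = 0.051), with a mean FPKM of at least 5 (0.18) and with quantile normalization (0.064), within a range of 0.0038 to 0.18. Of 4 measured markers of other cell types 3 rose, 4 adjusted over the list alone, among them the connective tissue proteoglycan LUM, from 3.24 ± 0.333 to 6.14 ± 0.534 FPKM (0.89 ± 0.12), and the keratin KRT10 (0.30 ± 0.07), with camera adjusted p = 0.08. With no filter 5 rose and the marker list was called (adjusted p = 0.024).

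Cytosolic ribosomal protein genes fell in 34 of 50 cases at 40 mM, also adjusted over the list alone (camera adjusted p = 9.8e-08, and adjusted p = 0.45 with an estimated correlation). RPLP0 was at -0.51 ± 0.05, RPL7 at -0.40 ± 0.07 and RPL18 at -0.38 ± 0.08. Processed pseudogenes of the family can share their reads. Replicate 3 of 40 mM, with the lowest ribosomal protein share, was not needed for the calls, since 35 fell without it, but the median went from -0.26 to -0.17. Leaving it out also changes the shared estimate of the spread, so a similar count does not show that it added little. With quantile normalization 9 fell and 5 rose (adjusted p = 0.31, the highest of a range from 3e-16). Ribosome biogenesis genes fell in 15 of 24 cases, also adjusted over the list alone (camera adjusted p = 8.7e-06, and adjusted p = 0.26 with an estimated correlation), with NOP56 at -0.95 ± 0.05 and NPM1 at -0.72 ± 0.03. Heat shock genes fell in 10 of 17 cases, also adjusted over the list alone, with HSP90AB1 at -0.87 ± 0.03 and HSPA8 at -0.75 ± 0.07 (camera adjusted p = 0.0012, and adjusted p = 0.43 with an estimated correlation). With quantile normalization the heat shock call was lost (adjusted p = 0.073, range 2.1e-06 to 0.073). G2/M genes fell in 14 of 25 cases and rose in 2, 15 and 3 adjusted over the list alone, with HMMR at -1.36 ± 0.05 and CDC20 at -0.55 ± 0.04 (camera adjusted p = 0.002, and adjusted p = 0.41 with an estimated correlation). With TPM scaling or quantile normalization 5 rose and 12 fell.

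In the TCA cycle list 14 of 23 fell and 2 rose at 40 mM, 15 and 2 adjusted over the list alone, with IDH2 at -0.90 ± 0.10, OGDH at -0.83 ± 0.06 and MDH1 at -0.64 ± 0.07 (camera adjusted p = 0.0014, and adjusted p = 0.11 with an estimated correlation). Nuclear-encoded genes of complexes III to V fell in 16 of 35 cases, 11 adjusted over the list alone, with the ATP synthase subunits ATP5PD at -0.57 ± 0.06 and ATP5F1A at -0.40 ± 0.07 (camera adjusted p = 0.0096, and adjusted p = 0.54 with an estimated correlation). Leaving out replicate 3 of 40 mM, 13 fell and 1 rose (adjusted p = 0.042). With TPM scaling, and also with quantile normalization, 6 fell and 3 rose. The call was lost with quantile normalization (0.25) and with library weights (0.072), within a range of 5.2e-05 to 0.25. Genes of complex I fell in 10 of 37 cases and rose in 2, 9 and 1 adjusted over the list alone (camera adjusted p = 0.13), with NDUFV3 at -0.80 ± 0.09 and NDUFV1 at -0.34 ± 0.05. The share that fell was near that of all tested genes, of which 3391 of 12394 were lower. The complex I median of -0.08 became 0.00 with TPM scaling, which moved the median of all genes from 0.00 to 0.08, and 5 complex I genes fell and 5 rose. Without replicate 2 of 40 mM the camera adjusted p was 0.042, within a range of 0.01 to 0.59. Without replicate 3 of 40 mM, 9 fell and 4 rose (adjusted p = 0.59). Of 13 mitochondrially encoded mRNAs, 3 fell and 1 rose, 2 and 1 adjusted over the list alone (camera adjusted p = 0.78), and 8 fell without replicate 3 of 40 mM. Without replicate 1 of 40 mM 4 rose and 2 fell, and without replicate 3 of 0 mM 1 rose and 0 fell.

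Of the remaining lists at 40 mM, cholesterol synthesis genes fell in 11 of 24 cases and rose in 3, also adjusted over the list alone, led by PMVK (-0.95 ± 0.10), with camera adjusted p = 0.08. It was 0.032 without replicate 1 of 40 mM, within a range of 0.0089 to 0.27, and 7 fell without replicate 1 of 0 mM. MAPK pathway output genes rose in 11 of 19 cases and fell in 2, 12 and 3 adjusted over the list alone, with DUSP5 at 1.48 ± 0.14 and EGR1 at 0.83 ± 0.20 (camera adjusted p = 0.057). That list was called without replicate 3 of 0 mM (adjusted p = 0.045) and without replicate 1 (0.034) or 2 (0.042) of 40 mM, within a range of 0.0089 to 0.089. It was also called with no filter (0.0089), TPM scaling (0.038) and quantile normalization (0.022). Glycolysis genes fell in 12 of 23 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 0.11), with LDHB at -0.55 ± 0.07 and GAPDH at -0.53 ± 0.04, and 5 rose without replicate 3 of 40 mM. With TPM scaling 7 rose and 7 fell, and with quantile normalization 4 and 6. With no filter glycolysis was called (adjusted p = 0.005), within a range of 0.005 to 0.91. Fatty acid synthesis was mixed, with FASN at -0.80 ± 0.07 and LPIN1 at 0.50 ± 0.07 (camera adjusted p = 0.8). Unfolded protein response genes fell in 9 of 19 cases and rose in 6, 10 and 6 adjusted over the list alone (camera adjusted p = 0.21), and 3 rose without replicate 2 of 0 mM or replicate 1 of 40 mM. BCL2 family genes rose in 5 of 11 cases and fell in 1, also adjusted over the list alone, with BBC3 at 1.01 ± 0.13 and PMAIP1 at 0.94 ± 0.08 (camera adjusted p = 0.27). With no filter that list was called (adjusted p = 0.018), 6 rose and 2 fell, and its median was 0.36 against 0.05. In the melanocyte lineage 3 of 9 rose and 1 fell, 3 and 3 adjusted over the list alone (camera adjusted p = 0.83), with GPNMB among the risers and ERBB3 at -0.64 ± 0.10. Its median of -0.07 and mean of 0.03 differed in sign, its test pointed up, and with TPM scaling its test pointed down. Its median then became 0.00, where that of all genes moved to 0.08.

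**Figure D2:**
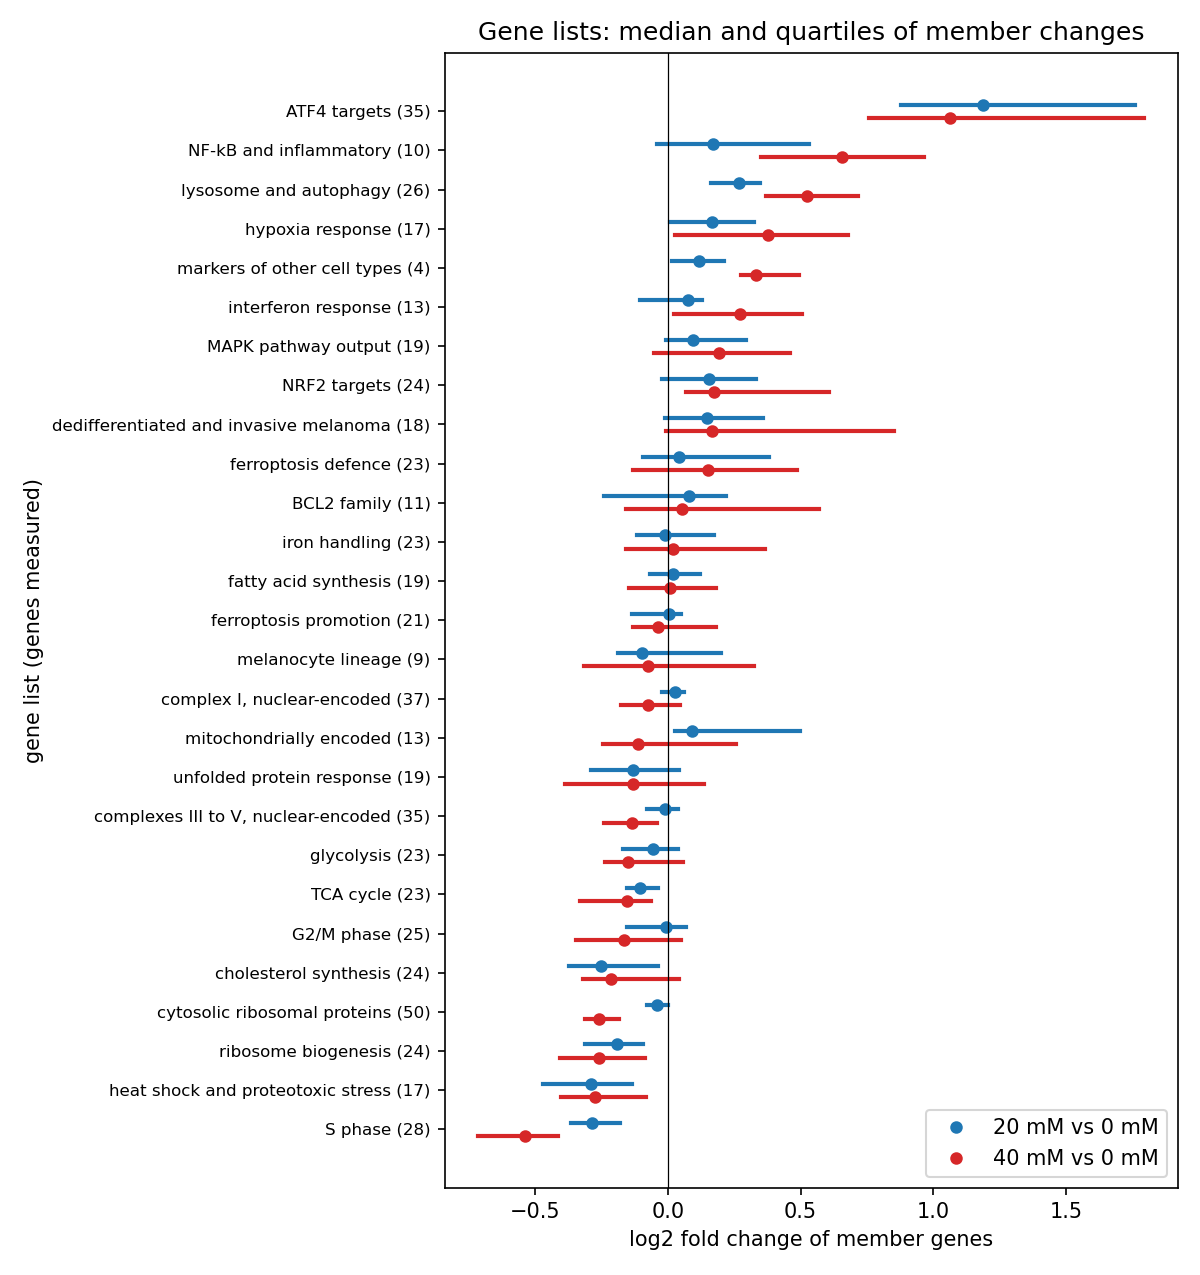
Median (point) and quartiles (line) of the log2 fold changes of each list's measured genes, horizontal axis, at 20 mM (blue) and 40 mM (red) against 0 mM; the number of genes stands after each list's name. ATF4 targets lie farthest up, with medians of 1.19 and 1.06, and S phase genes farthest down at 40 mM, with a median of -0.54.

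By the edgeR test, 6962 of 12394 genes differed between 40 and 0 mM, 3571 higher and 3391 lower, with 273 higher and 184 lower by at least 2-fold. Higher genes made up 51.3% of the calls, and 64.0% with TPM scaling. Quantile normalization brought the ribosomal protein median at 40 mM to -0.06 and turned it to 0.04 at 20 mM. Leaving out replicate 3 of 40 mM gave 7135 genes, of which 6464 were shared.

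The comparison of 40 mM with 20 mM asks what the step between the doses changed. S phase genes fell further, in 23 of 28 cases, also adjusted over the list alone, with E2F2 at -0.80 ± 0.12 (camera adjusted p = 1.5e-12, and adjusted p = 0.13 with an estimated correlation). The growth-factor-like CCN1 rose by 1.14 ± 0.06 (adjusted p = 9.2e-06), JUN by 1.21 ± 0.17, RN7SK by 2.81 ± 0.41 and MT-TL1, a mitochondrial tRNA gene, by 1.11 ± 0.12. The integrin ITGB3 fell by 1.08 ± 0.10, the autophagy-linked DAP by 0.95 ± 0.07 and the chromatin protein NUCKS1 by 0.92 ± 0.05. ACSL4 fell further, by 0.60 ± 0.07 (adjusted p = 0.00023).

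ATF4 fell by 0.20 ± 0.04 (adjusted p = 0.0074). SLC7A11 was called at -0.17 ± 0.05 (adjusted p = 0.027), but not without replicate 2 (-0.14, adjusted p = 0.12) or 3 (-0.16, 0.081) of 20 mM or replicate 2 of 40 mM (-0.17, 0.061). CHAC1 at -0.28 ± 0.07 (adjusted p = 0.017) was not called without replicate 2 (0.061) or 3 (0.075) of 20 mM or replicate 2 of 40 mM (0.056). DDIT3 at 0.43 ± 0.11 (adjusted p = 0.015) was not called without replicate 1 (0.056) or 2 (0.058) of 20 mM or replicate 2 of 40 mM (0.053). HMOX1 at 1.08 ± 0.32 (adjusted p = 0.028) was at 0.56 without replicate 1 of 40 mM (adjusted p = 0.093), and was not called without replicate 2 (0.091) or 3 (0.10) of 20 mM. FTH1 at 0.27 ± 0.07 (adjusted p = 0.015) was not called without replicate 2 (0.063) or 3 (0.067) of 20 mM or replicate 1 of 40 mM (0.053). GPX4 (-0.03 ± 0.05, adjusted p = 0.64), TFRC (-0.01 ± 0.07, adjusted p = 0.91) and NFE2L2 (0.07 ± 0.06, adjusted p = 0.42) did not pass. With 1 library left out they ran from -0.08 to -0.01, from -0.07 to 0.07 and from 0.00 to 0.10. TXNIP (0.44 ± 0.15, adjusted p = 0.055) and SOD2 (0.13 ± 0.05, adjusted p = 0.091) did not pass either, but both did without replicate 3 of 40 mM (0.50, adjusted p = 0.043, and 0.19, adjusted p = 0.0096), and TXNIP without replicate 3 of 20 mM (0.55, adjusted p = 0.043). The readthrough gene NDUFC2-KCTD14 rose by 1.21 ± 0.27 and overlaps its parent genes. CHMP4A was called at -1.45 ± 0.44 (adjusted p = 0.03), and its adjusted p lay between 0.0501 and 0.091 without replicates 1, 2 or 3 of 20 mM or replicates 1 or 3 of 40 mM.

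Lysosome and autophagy genes rose in 17 of 26 cases between 20 and 40 mM, also adjusted over the list alone, with GABARAPL1 at 0.64 ± 0.06 (camera adjusted p = 3.2e-09, and adjusted p = 0.092 with an estimated correlation). NF-kB and inflammatory genes rose in 6 of 10 cases, 7 adjusted over the list alone, with ICAM1 at 0.65 ± 0.06 (camera adjusted p = 0.00054, and adjusted p = 0.092 with an estimated correlation). Dedifferentiated and invasive melanoma genes rose in 8 of 18 cases and fell in 2, 9 and 2 adjusted over the list alone, with CCN2 at 0.78 ± 0.12 (camera adjusted p = 0.01, and adjusted p = 0.6 with an estimated correlation). Interferon genes rose in 6 of 13 cases, 7 adjusted over the list alone, with IFIT2 at 0.72 ± 0.14 (camera adjusted p = 0.0076, and adjusted p = 0.13 with an estimated correlation). Without replicate 2 of 20 mM 2 rose. With a mean FPKM of at least 5 the interferon call was lost (adjusted p = 0.08, range 0.0031 to 0.08). G2/M genes fell in 14 of 25 cases, 15 adjusted over the list alone, with HMMR at -0.84 ± 0.05 (camera adjusted p = 3.8e-06, and adjusted p = 0.21 with an estimated correlation). The G2/M fallers were 8 or 9 without replicate 1 or 2 of 20 mM, 6 with TPM scaling and 8 with quantile normalization. Ribosomal protein genes fell in 31 of 50 cases, 36 adjusted over the list alone, with RPL3 at -0.32 ± 0.04 (camera adjusted p = 1.4e-10, and adjusted p = 0.5 with an estimated correlation). The ribosomal protein fallers were 15 without replicate 2 or 3 of 20 mM, 8 with TPM scaling and 5 with quantile normalization. Without replicate 3 of 40 mM, whose ribosomal protein share was lowest, 31 fell as well, but the median went from -0.20 to -0.13.

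Smaller calls between the doses, or their counts of members, depended more on single libraries or scaling. Complexes III to V fell in 5 of 35 cases, 1 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.62 with an estimated correlation). There was 1 faller with TPM scaling or without replicate 2 or 3 of 20 mM, 3 without replicate 1 of 40 mM, and 8 or 9 without replicate 2 or 3 of 40 mM. At the preset correlation the camera adjusted p of complexes III to V ran from 4.9e-07 to 0.041, so that call was kept. The share that fell was near that of all tested genes, of which 1867 of 12394 were lower. Complex I fell in 7 of 37 cases, 6 adjusted over the list alone, with NDUFB5 at -0.39 ± 0.07 (camera adjusted p = 0.011, and adjusted p = 0.62 with an estimated correlation). It was not called without replicate 3 of 40 mM (0.18), with quantile normalization (0.052) or with library weights (0.22), within a range of 3.8e-05 to 0.22. TCA cycle genes fell in 7 of 23 cases, also adjusted over the list alone, with IDH2 at -0.84 ± 0.10 (camera adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation). TPM scaling ended that call (0.085, range 7.9e-05 to 0.09). It also turned the median from -0.05 to 0.02, but moved the median of all genes from 0.00 to 0.07. Ribosome biogenesis genes fell in 9 of 24 cases and 1 rose, 10 and 1 adjusted over the list alone, with NOP56 at -0.43 ± 0.05 (camera adjusted p = 0.017, and adjusted p = 0.62 with an estimated correlation). They were not called without replicate 1 of 20 mM (0.087, range 5.6e-05 to 0.14), and 3 fell with TPM scaling. Hypoxia genes rose in 7 of 17 cases and fell in 2, also adjusted over the list alone, with NDRG1 at 0.73 ± 0.07 (camera adjusted p = 0.04, and adjusted p = 0.36 with an estimated correlation). They were not called without replicate 3 of 20 mM (0.058) or replicate 1 of 40 mM (0.059), within a range of 0.025 to 0.18. Markers of other cell types rose in 2 of 4 cases, also adjusted over the list alone, with LUM at 0.52 ± 0.12 and KRT14 at 0.36 ± 0.08 (camera adjusted p = 0.04, and adjusted p = 0.21 with an estimated correlation). They were not called without replicate 1 (0.068) or 2 (0.058) of 40 mM, within a range of 0.0023 to 0.18. ATF4 targets fell in 14 of 35 cases and rose in 5, 17 and 7 adjusted over the list alone, with SESN2 at -0.36 ± 0.07 (camera adjusted p = 0.047, and adjusted p = 0.62 with an estimated correlation). Without replicates 1 (0.058), 2 (0.051) or 3 (0.057) of 0 mM, 2 (0.053) or 3 (0.11) of 20 mM, or 2 (0.098) or 3 (0.066) of 40 mM, that list was not called, within a range of 0.0023 to 0.26, and 3 rose without replicate 1 of 20 mM. The TCA cycle, ribosome biogenesis and hypoxia calls were each also lost with a filter at 5 FPKM, TPM scaling, quantile normalization and library weights. Markers of other cell types lost theirs with that filter and TPM scaling, and ATF4 targets with the 6 libraries compared alone and with limma on log2(FPKM + 1), quantile normalization or library weights.

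Mitochondrially encoded genes were not called between the doses (camera adjusted p = 0.052), with 3 of 13 falling and 1 rising, also adjusted over the list alone. Without replicate 3 of 40 mM, whose mitochondrial share was highest, 11 fell and the camera adjusted p was 0.00013. They were also called without replicate 1 (0.048) or 3 (0.045) of 0 mM and replicate 2 of 20 mM (0.049), within a range of 0.00013 to 0.34. Calls came too with no filter (0.004), TPM scaling (0.023), only the 6 libraries compared (0.043), each pseudocount in limma (0.047 to 0.049) and library weights (0.0029). Without the same 40 mM library iron handling (0.028) and NRF2 targets (0.041) were called as rising, against 0.098 and 0.34 with it, within ranges of 0.028 to 0.24 and 0.041 to 0.77. These lists share HMOX1, FTH1 and FTL. Camera adjusted p was 0.89 for ferroptosis defence, 0.45 for ferroptosis promotion, and between 0.31 and 0.96 for 8 other lists. Among those, heat shock had a median of -0.03 and a mean of 0.04 with its test pointing up.

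By the edgeR test 3637 of 12394 genes differed between 40 and 20 mM, 1770 higher and 1867 lower, with 39 higher and 19 lower by at least 2-fold. Without replicate 2 or 3 of 20 mM 1142 or 1154 genes were higher. Higher genes made up 48.7% of the calls, and 71.1% with TPM scaling. Leaving out replicate 3 of 40 mM gave 4065 genes, of which 3245 were shared.

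Both doses were then compared over the same genes. Of the 12394 genes, 1811 were higher and 1620 lower at both doses against 0 mM, and 16 moved in opposite directions. Independent calls would give 583 and 516 shared genes. Unchanged groups, simulated around the mean of the controls with 3 simulated control libraries in common, gave 0.05 in each direction on average over 20 simulations. Without any effect almost nothing is called, so that count does not measure what shared controls add to the shared genes. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.782, against a simulated mean of 0.506 (range 0.330 to 0.665). Their covariance was 0.139, against 0.0174 simulated, a difference of 0.122. With 3 controls these could not be split, so part of the excess of shared genes and of r may come from the shared controls. Among genes called in the same direction at both doses, the change at 40 mM was 1.46 times that at 20 mM in the median. From 0 to 20 and from 20 to 40 mM, 681 genes rose at both steps and 717 fell at both, while 133 rose and then fell and 108 fell and then rose. Both steps use the same 20 mM libraries with opposite sign. The spread of those libraries can therefore add to the 133 and 108 and take from the 681 and 717. The 1398 genes that moved the same way at both steps were 882, 806 and 881 without replicates 1, 2 and 3 of 20 mM.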

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

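Most results of genes under the naming rule kept their direction and side of the threshold: of 6640 values for 292 gene results under the alternatives, 6281 were the same, 342 weaker, 16 stronger and 1 reversed. Most of these genes were picked from the same libraries for large called changes. That choice favoured agreement, which does not extend to the other called genes. The reversed value was RPLP0 at 20 against 0 mM, at 0.0132 with quantile normalization. DESeq2 called 4454, 7239 and 4126 genes for 20 against 0, 40 against 0 and 40 against 20 mM, of which 3896, 6914 and 3623 were shared with edgeR. The limma test on FPKM called 3647, 6886 and 3528, with 3518, 6513 and 3132 shared. On simulated data with this depth and spread, edgeR recovered 80%, 70% and 82% of 1.5-fold changes, so real changes of that size can be missed.

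Higher and lower genes numbered 1324 and 1193 at 20 against 0 mM, 2168 and 2077 at 40 against 0 mM and 1174 and 1193 at 40 against 20 mM with a filter at 5 FPKM, where fewer genes were tested. With a log2 fold change of at least 1 they numbered 98 and 31, 273 and 184, and 39 and 19. At an adjusted p under 0.01 they numbered 1168 and 999 at 20 against 0 mM and 868 and 990 at 40 against 20 mM; both limits are stricter by construction. Between 40 and 20 mM, TPM scaling gave 2832 higher and 1153 lower genes and moved the median of all genes to 0.07, a common shift from the scaling. Library weights gave 2899 higher; the cause was not tested. Of the 28 lists, an estimated correlation left 1, 2 and 0 called in the 3 comparisons, and fry called 16 at 20 mM and 25 at 40 mM. With no filter 16 lists were called at 20 mM, and the ferroptosis defence mean was 0.153 (camera adjusted p = 0.018, range 0.018 to 0.15); between 40 and 20 mM the filter at 5 FPKM and quantile normalization each called 9. The cause was not tested. The correlation of the doses was 0.551 with no filter and 0.682 with DESeq2, and 906 genes changed stepwise with no filter; the cause was not tested.

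Leaving out 1 library at a time gave 1432 to 2498 higher and 1274 to 2468 lower genes at 20 against 0 mM, 3092 to 3631 and 2957 to 3504 at 40 against 0 mM, and 1142 to 1966 and 1266 to 2099 at 40 against 20 mM. Lists called were 9 to 12, 14 to 16 and 12 to 15. The mean of ferroptosis defence ran from 0.148 to 0.180, 0.139 to 0.191 and -0.02 to 0.03, and that of ferroptosis promotion from -0.01 to 0.01, 0.02 to 0.06 and 0.02 to 0.05. The correlation of the doses ran from 0.693 to 0.816 and the stepwise genes from 806 to 1731.

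With a replicate block, counts were 2199 and 2046, 3668 and 3547, and 1948 and 2034, with 10, 15 and 15 lists. With the block the MAPK list at 40 against 0 mM (adjusted p = 0.035) and mitochondrially encoded genes at 40 against 20 mM (0.014, 7 fell) were called, as were HMOX1 at 20 against 0 mM (0.50, 0.015) and TXNIP at 40 against 20 mM (0.44, 0.041). The numbers were not taken as a pairing, since the labels state none and same-number correlations ran from -0.0421 to 0.222, not all above 0.1. As a hint from the data, other pairs ran from -0.222 to 0.0882, and 6 of 9 libraries, not all, correlated best with their own number.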

Other observations

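Gene groups outside the lists were examined as 287 pathways of the deposited annotation, and both the pathways and the genes named here were chosen only after results were seen. At 40 against 0 mM, proteasome genes fell in 25 of 42 cases and rose in 2 (median -0.23, camera adjusted p = 0.00014, and adjusted p = 0.8 with an estimated correlation), among them PSMD7 (-0.82 ± 0.05), PSMD4 (-0.54 ± 0.06) and PSMD13 (-0.52 ± 0.07), while the immunoproteasome subunit PSMB9 rose by 0.53 ± 0.15. Mismatch repair genes fell in 15 of 21 cases and 1 rose (camera adjusted p = 0.00042, and adjusted p = 0.48 with an estimated correlation), with the DNA ligase LIG1 at -1.34 ± 0.06 and MSH6 at -0.81 ± 0.04; PMS2 (-1.18 ± 0.07) has many pseudogene copies, and the set shares PCNA and RFC2 with the S phase list. Of 63 cytokine and receptor genes 35 rose and 9 fell (camera adjusted p = 0.0056, and adjusted p = 0.48 with an estimated correlation), including the cytokine IL24 (1.34 ± 0.11) and the activin subunits INHBE (5.07 ± 0.57) and INHBA (1.26 ± 0.07). Mineral absorption genes rose in 14 of 22 cases and 1 fell (camera adjusted p = 0.0032, and adjusted p = 0.48 with an estimated correlation), with the metallothioneins MT1X (1.44 ± 0.20) and MT2A (0.67 ± 0.07), whose family members share sequence, and the copper importer SLC31A1 (0.81 ± 0.06). No pathway was called with an estimated correlation, and the smallest adjusted p was 0.15.

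Tests of the next patterns were chosen only after results were seen. Their 95% intervals come from resampling genes, which are not independent replicates. The spread between libraries does not enter these intervals, so what they argue against holds for these libraries only. Mitochondrial tRNA genes fell in 18 of 22 cases at 20 mM and 21 of 22 at 40 mM, with medians of -0.85 and -0.78, while the 2 mitochondrial rRNAs had medians of 0.52 and 1.24. At 20 mM 71 nuclear short noncoding genes had a median change 0.0049 times that of the tRNAs (95% interval -0.0962 to 0.129). At 40 mM the ratio was 0.346 (0.119 to 0.509) with all libraries and 0.148 (-0.00115 to 0.375) without replicate 3 of 40 mM. So these genes as a set did not fall with the tRNAs at 20 mM. Oligo(dT) captures polyadenylated RNA, so their reads may come from longer overlapping transcripts. The ratio therefore cannot decide on loss of short RNAs, which stays open at both doses. Reads from neighbouring transcripts are argued against by a median difference of -1.08 to the nearest rRNA or mRNA gene at 20 mM (-1.31 to -0.86) and -0.98 at 40 mM (-1.33 to -0.82). The nearest gene was taken by position, without regard to strand. MT-TQ, MT-TA, MT-TN, MT-TC, MT-TY, MT-TS1 and MT-TP were paired with genes of the other strand. If counting used strand, those pairs do not test this explanation. A common fall of mitochondrial transcripts is argued against at 20 mM, where the 15 rRNA and mRNA genes had a median of 0.19 (0.05 to 0.55). At 40 mM that median was -0.05 (-0.24 to 0.28). Without replicate 3 of 40 mM it was -0.22 (-0.35 to 0.06) against a tRNA median of -1.03, and 8 of 13 mRNAs fell. At 40 mM a part of the tRNA fall may therefore come from a common fall. These values are transcript levels and not rates, so lower transcription of the whole mitochondrial genome was not tested directly and stays open. Changed processing or turnover of the precursors could remain and was not tested.

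Cytosolic ribosomal protein genes had a median change of -0.26 at 40 mM. Replicate 3 of 40 mM alone is argued against, since 35 members fell without it and the median was -0.17. Genes matched on level and annotated transcript length changed 0.388 times as much (0.118 to 0.559), while those matched on the length implied by counts and FPKM, the measure first intended, changed 0.779 times as much (0.613 to 1.09). Without replicate 3 of 40 mM the ratio by annotated length was 0.538 (-0.00866 to 0.691). The length measure was changed after a first, faulty value was seen, and the measures differ. Loss of short transcripts could account for part of the fall, or for all of it by the measure first intended, and stays open.

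BEST1 overlaps FTH1 from 61959718 to 61964461 on chromosome 11, and its change at 20 mM exceeded that of FTH1 by 3.73 ± 0.50, which argues against a fixed share of FTH1 reads. A share that changed with dose could remain and was not tested.

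Each comparison's 6 libraries can be split in 10 ways, too few for a share under 0.05. For genes called, the real split gave 3911, 6962 and 3637 and the highest other 0, 0 and 2, so 1, 1 and 1 of 10 were as large. For lists called, the real split gave 10, 14 and 14 and the highest other 11, 12 and 12, so 3, 1 and 1 of 10 were as large.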
